A study of Homo sapiens with 2 samples.

How the data were processed

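RNA from HUH7 cells, a human hepatocellular carcinoma line, was measured by RNA immunoprecipitation and sequencing in 2 libraries: RNA recovered with an anti-ZMAT2 antibody (ZMAT2 IP) and RNA of the unfractionated lysate (Input). Per the labels' protocols, most of the lysate went into the precipitation, smaller shares were set aside as Input and for a rabbit IgG control, RNA was extracted with TRIzol, and libraries were made with a stranded mRNA kit. The IgG control was not analysed here. Each group held 1 library, named from its title.

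The deposited table holds whole-number read counts per gene, not normalized, for 56303 genes, with exon coordinates and merged exon length, per the file headers. The submitters' processing notes name fastp 0.23.4, STAR 2.5.3a, edgeR 3.12.1 and the genome build GRCh38. The counting tool, its settings and the annotation release are not given in the sources used here. The values themselves bear on 3 features of the counting. First, mates of a read pair appear to have been counted one by one: among genes with 1 to 6 reads, 77.9% of the IP counts and 67.1% of the Input counts were even numbers. Second, reads in exons of overlapping genes appear to have been counted for each: in 454 pairs of a gene with 20 or more reads and another gene whose exons hold it wholly, on either strand, the inner gene had no more reads than the outer in both libraries for all 454. By position, 6836 of the kept genes (38.2%) share at least 5% of their exon bases with another gene on either strand. Last, strand may not have been used: of 774 genes that lie almost wholly within exons of the opposite strand, 325 had 20 or more reads. Antisense transcripts of these genes could give such reads too, so this count does not decide it. Overlapping genes cannot be told apart where they share exon bases, and this may hold for antisense genes too. For genes named here that share at least 5% of their exon bases the percentage is given.

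Gene names were brought up to date through the RefSeq gene table of GRCh38.p14, which also gave the gene biotypes: 33451 names matched by symbol and position, 1748 by an older symbol and position, 37 mitochondrial genes by position within 5 bases, and 21067 did not match and kept the table's name. The summed length of merged exon intervals equalled the deposited length for all but 10 genes. Exon blocks, exon length and gene span were taken from the deposited coordinates, which are of the authors' build. GC content was not computed, because no genome sequence was used here.

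The 2 libraries held 25047635 and 23485789 reads in genes. Because reads without molecular identifiers are not independent molecules, all intervals and floors cover counting error only. A count of 0 was treated as allowing up to 3 reads, equal to 0.12 CPM in the IP and 0.128 CPM in Input, and a fold against a count of 0 is given as a lower bound against these 3 reads in that library. This bound leaves out the counting error of the other library, so the interval bound is given beside it.

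With 1 library per group there is no replicate, so edgeR's quasi-likelihood test could not be run, no p-value across genes is given, and each difference is one between these 2 libraries without a replicate check. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, computed over the genes with at least 20 reads in both libraries together (17915 genes kept). The log2 ratio of IP over Input used a prior count of 0.5. Its 95% interval is the exact (Clopper-Pearson) interval of the IP share of a gene's reads. A gene was called higher or lower in the IP when the ratio was at least 2-fold and the interval excluded 0 on the log2 scale. Since mates were counted separately, these intervals are too narrow, and a second set was computed on pairs, taking 2 reads as 1.

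For each of 32 gene lists, the median log2 ratio of its kept members minus that of all kept genes is called the shift. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is not a test of conditions. A list is said to stand outside when its median lies beyond the middle 95% of these random lists. A percentile of 0 or 100 means that the median lay beyond every random list. Lists with fewer than 3 kept genes were not given a shift. The Pearson and Spearman correlations of log2 (CPM + 1) and the rank correlations with gene structure are across genes, which are not independent replicates.

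The design, the gene lists, most of the alternatives and the rule for naming genes were set before the data were examined. The rule takes the 10 protein-coding genes with the highest lower interval bound and the 10 with the lowest upper bound, 4 and 4 genes of other biotypes by the same bounds, ZMAT2 and TRIM28, and from each list the 2 members with the most reads and the member farthest from the median of all genes, thinned where not needed. One gene that the rule takes is not reported here. Genes named outside this rule are marked as chosen after their values were seen. The alternatives were other scalings (library totals, DESeq2 1.42.0 size factors, upper quartile, totals without mitochondrial genes), other read minimums (1 and 100), prior count 5, a 1.5-fold or 4-fold rule, an interval wholly beyond 2-fold, protein-coding genes alone, and random lists matched on exon length as well. Intervals on pairs of reads, genes sharing under 5% of their exon bases, a minimum of 1000 reads and the list of tri-snRNP proteins without ZMAT2 were added after seeing the data.

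The rule and the list percentiles were tested on simulated counts drawn for the 17915 kept genes from the IP and Input means, with 50 genes changed at each of 4 sizes. Of these, 98% were called higher at a 3-fold change, 100% at 4-fold and at 8-fold, and 8% at 1.5-fold. Among 17715 unchanged genes, 43 were called higher and 37 lower, and 95.7% of intervals held the true ratio. Of 100 random lists, 8 lay outside the middle 95%. The simulation drew counting error alone, without duplicate reads or variation between precipitations. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.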

Results

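The data comprised 1 library of RNA precipitated with an antibody against ZMAT2 and 1 Input library of the same HUH7 cell lysate preparation. ZMAT2 is the human counterpart of yeast Snu23, a zinc-finger protein that joins the spliceosome with the tri-snRNP as the B complex forms. The IP library held 25047635 reads in genes and the Input library 23485789. At least 1 read was counted for 24075 genes in the IP and for 25472 genes in Input, and the 10 most abundant genes took 8.44% and 6.91% of the reads. Values are reads per gene from the deposited counts, scaled by TMM, and each comparison is between these 2 libraries, without replicates. Intervals are 95% counting intervals.

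The stated aim concerned whether ZMAT2 acts on the progression of hepatocellular carcinoma through its splicing function, and the study's title names the alternative splicing of TRIM28. Both genes were higher in the IP. ZMAT2, at 140698680 to 140706676 on chromosome 5 (GRCh38), had 36553 reads in the IP and 5187 in Input, or 1514 and 212.9 CPM, a log2 ratio of 2.83 (2.79 to 2.87) or 7.11-fold. It shares 8.39% of its exon bases with another gene. TRIM28 encodes the corepressor that KRAB zinc finger proteins recruit to chromatin and lies at 58544091 to 58550722 on chromosome 19. It had 4800 reads in the IP and 2215 in Input, or 198.8 and 90.93 CPM, a log2 ratio of 1.13 (1.06 to 1.20) or 2.19-fold. Counted in pairs of reads, its interval was 1.03 to 1.23. Among 12951 protein-coding genes, 41 had a higher ratio than ZMAT2 (0.317%) and 637 a higher ratio than TRIM28 (4.92%). Among the 6596 protein-coding genes with at least 1000 reads, these numbers were 12 and 170. Counts per gene do not separate isoforms or introns, so splicing of TRIM28 was not analysed here.

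Across genes, the question was which RNAs stood higher in the IP than in Input relative to the bulk of genes. TMM centres the ratios on that bulk (median log2 ratio 0.0059), so they do not measure absolute recovery. Since the IgG control was not analysed here, a higher ratio does not by itself show binding to ZMAT2. Reads in the mitochondrial tRNA genes, which need not be of mature tRNAs, and the mRNAs of 3 myosin heavy chains were among the highest in the IP. Signal recognition particle RNA, 7SK RNA and MALAT1 were among the abundant RNAs that stood lower. Of the 17915 genes kept, 1328 (7.41%) were called higher in the IP and 1248 (6.97%) lower, at least 2-fold and with an interval that excluded 0. Within 2-fold lay 84.8% of genes, and genes neither called nor within 2-fold had an interval that included 0. With library totals in place of TMM, which moved the median log2 ratio of all genes by -0.106, the counts were 1023 higher and 1561 lower, and the share of calls that were higher went from 51.6% to 39.6%. The libraries correlated across genes with a Pearson r of 0.969 and a Spearman rho of 0.967. Of the called genes, 539 higher and 698 lower ones had fewer than 100 reads. For genes with 20 to 39 reads the SD of the log2 ratio over genes was 1.44, against 0.55 from counting reads, so calls at such depth are uncertain.

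**Figure D1:**
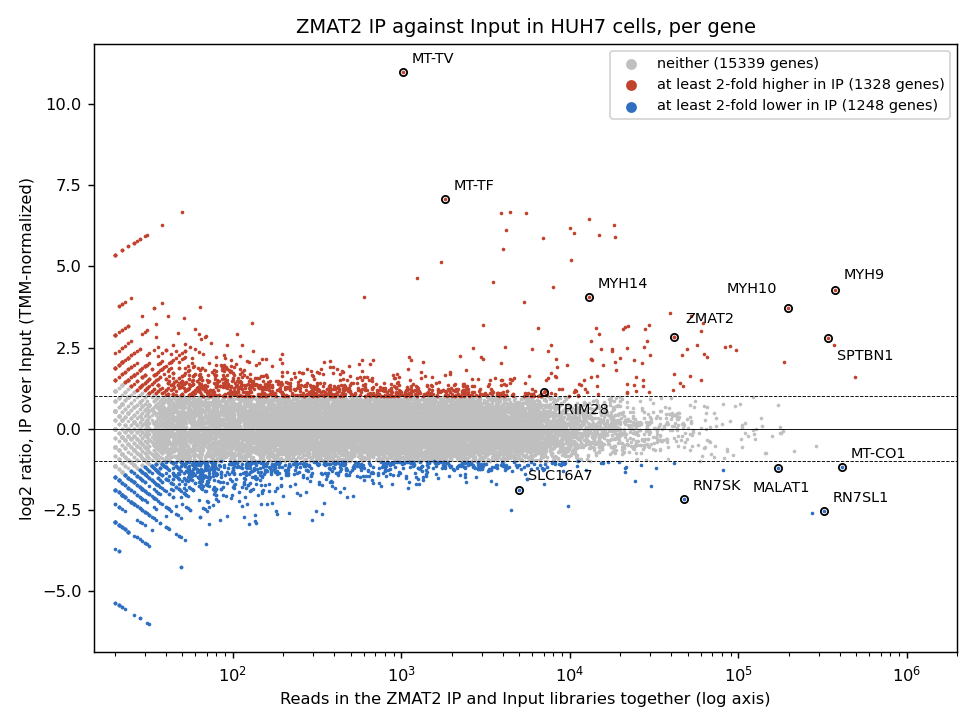
Each point is a kept gene, with its reads in both libraries together on a log axis and its log2 ratio of ZMAT2 IP over Input on the vertical axis. Dashed lines mark 2-fold, red and blue points are the 1328 higher and 1248 lower genes, and the height of points with no read in one library, such as MT-TV, depends on the prior count of 0.5.

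The mRNAs of all 3 non-muscle myosin II heavy chains, the motors that contract actin filaments, were among the 10 highest protein-coding genes. MYH9, at 36281281 to 36388018 on chromosome 22, had 356764 reads in the IP and 18569 in Input, a log2 ratio of 4.28 (4.26 to 4.30) or 19.4-fold. MYH14 on chromosome 19 had a log2 ratio of 4.05 (3.95 to 4.16) and MYH10 on chromosome 17 one of 3.73 (3.71 to 3.76). TMOD3, which encodes a tropomodulin that caps actin filaments and shares 6.2% of its exon bases with another gene, had a log2 ratio of 3.07 (3.02 to 3.13). The tight junction gene CGN, with 18421 reads in the IP and 2226 in Input, stood at 3.06 and UACA at 3.21 (3.15 to 3.27). The mitochondrial mRNAs MT-ND3 and MT-ATP8 had intervals of 3.22 to 3.30 and 3.04 to 3.20, the second gene sharing 22.2% of its bases with a neighbour. CCDC88B had 50 reads in the IP and 0 in Input, at least 16.8-fold higher against the floor of 3 reads, and the lower bound of its interval was a log2 ratio of 3.72, or 2.67 counted in pairs.

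The 10 protein-coding genes with the lowest upper bounds all had few reads. GPR180 had 26 reads in the IP and 154 in Input, a log2 ratio of -2.53 (-3.21 to -1.95). C1QL3 had 5 and 64 reads and a ratio of -3.54 (-5.34 to -2.37), RASGRP1 had 4 and 48 reads and a ratio of -3.42 (-5.51 to -2.12), and DIAPH2 had 4 and 44 reads and a ratio of -3.29 (-5.38 to -1.99). SLC2A12, which shares 38.9% of its exon bases, had 2 and 47 reads and a ratio of -4.24 (-7.63 to -2.61). CLEC7A had 2 and 30 reads (-3.60, -7.00 to -1.92) and INHBC 2 and 29 (-3.55, -6.96 to -1.86). IL17RD had no read in the IP and 26 in Input, at least 8.59-fold lower against the floor, with an upper interval bound of -2.70, or -1.60 in pairs. TMEM217, which shares 7.38% of its exon bases, and OGN had 0 and 22 reads each, at least 7.27-fold lower, with an upper bound of -2.44, or -1.31 in pairs.

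Reads from the mitochondrial genome made up 6.5% of the IP library and 2.66% of Input. All 22 mitochondrial tRNA genes were called higher, with a median log2 ratio of 5.94, and the highest genes of other biotypes were 4 of them. MT-TV had 1017 reads in the IP and 0 in Input, at least 342-fold higher against the floor, with a lower interval bound of 8.12, or 7.11 in pairs. MT-TF had a log2 ratio of 7.07 (6.35 to 8.03), MT-TE of 6.67 (6.25 to 7.15) and MT-TM of 6.63 (6.27 to 7.06). Of the 13 mitochondrial mRNAs, 10 were higher and 1 was lower, MT-CO1, with 126285 reads in the IP and 285979 in Input and a log2 ratio of -1.17 (-1.18 to -1.16). The list of mitochondrially encoded mRNAs and rRNAs had a shift of 2.51, beyond all 10000 random lists, with MT-RNR1 farthest from the median at 4.37 (4.22 to 4.52) and MT-ND5 at 1.61 (1.60 to 1.62). Nuclear-encoded respiratory chain genes had a shift of 0.00, and none of 48 passed 2-fold.

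**Figure D2:**
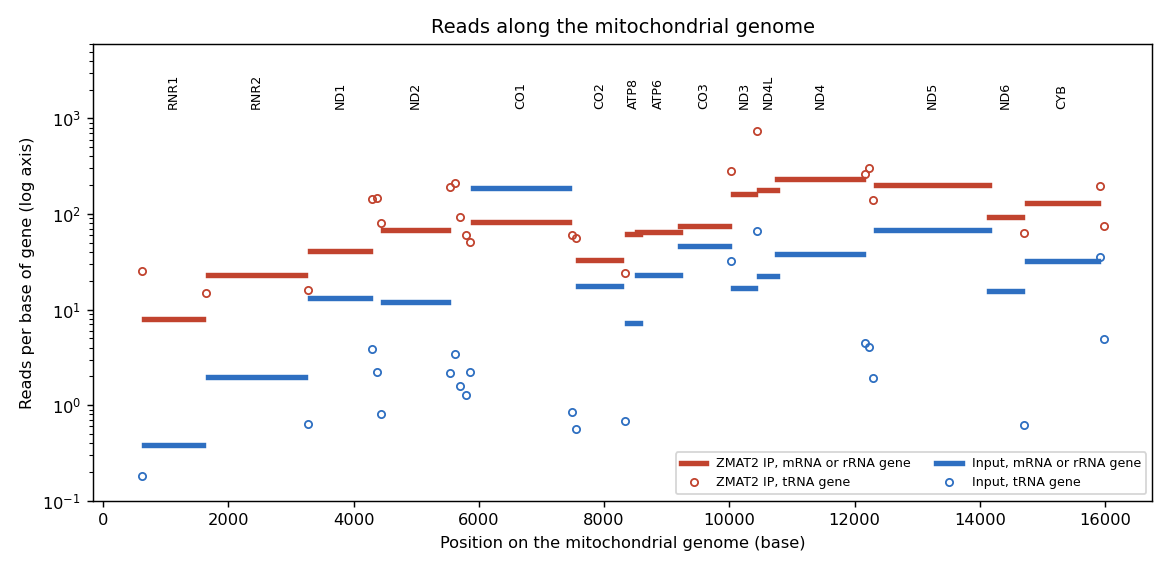
Reads per base of each mitochondrial gene (log axis) are drawn against its position in bases, as bars for mRNA and rRNA genes and circles for tRNA genes, with the IP in red and Input in blue. All 22 tRNA genes were higher in the IP, MT-CO1 was the 1 mRNA called lower, and MT-TV has no Input circle because it had 0 reads there.

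Several abundant small RNAs transcribed by RNA polymerase III were lower in the IP. The libraries were made with an mRNA kit, and whether it kept these RNAs equally in both was not tested. RN7SL1 and RN7SL2, which encode the RNA of the signal recognition particle and are near-identical copies that can share reads, had log2 ratios of -2.51 (-2.53 to -2.50) and -2.58 (-2.60 to -2.57). RN7SK, which encodes the 7SK RNA that holds back transcription elongation, was at -2.14 (-2.18 to -2.11), chosen after its value was seen. The list of other small nuclear, nucleolar and polymerase III RNAs took 0.442% of IP reads and 2.46% of Input reads. By gene it held 4 higher and 6 lower members of 20, with SCARNA7, chosen after its value was seen, at 2.59 (1.86 to 3.49), and its shift of 0.24 lay at the 90.6th percentile, while the mean differed in sign at -0.15 and the shift was -0.20 at a minimum of 100 reads and -0.17 at 1000. Also among the lowest genes of other biotypes, the pseudogenes MFSD1P1 and HMGN1P8 had no read in the IP and 32 and 31 in Input, at least 10.6-fold and 10.2-fold lower, with upper interval bounds of -3.02 and -2.97, or -1.93 and -1.88 in pairs, and RNU6-1016P had 2 and 47 reads and a ratio of -4.24 (-7.63 to -2.61).

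Nuclear long noncoding RNAs had a shift of -0.75, below all random lists, with 5 of 13 lower and none higher. MALAT1, a nuclear speckle RNA that shares 23.3% of its bases with another gene, had 51344 reads in the IP and 119983 in Input and a log2 ratio of -1.21 (-1.23 to -1.20), NORAD, which is known to be mainly cytoplasmic, had the same ratio of -1.21 (-1.24 to -1.17), and NEAT1, the scaffold of paraspeckles, was at -1.71 (-1.79 to -1.63). Over all 820 lncRNA genes kept, 50 were higher and 86 lower, with a shift of -0.12. Host genes of snoRNAs had a shift of 0.05 and a mean of the opposite sign (-0.01), with 22 genes kept.

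Among the RNAs and mRNAs of the splicing machinery, most genes lay within 2-fold. The 10 spliceosomal snRNAs kept had 2 higher and 2 lower members and a shift of 0.14, at the 67.5th percentile, which became -0.23 at a minimum of 100 reads. Together they had 2696 reads in the IP and 5527 in Input, most of them in RNU2-2, from libraries made with an mRNA kit. Recovery of the spliceosomal snRNAs in the IP can therefore hardly be judged from these libraries. RNU2-2 had 2236 reads in the IP and 5080 in Input and a log2 ratio of -1.17 (-1.24 to -1.10), but all of its bases lie in exons of another gene, whose reads cannot be told from its own. RNU5E-1 had 45 and 7 reads and a ratio of 2.61 (1.54 to 4.09). The list of tri-snRNP and B complex proteins, to which ZMAT2 belongs, had 3 higher and 1 lower of 25 and a shift of 0.25 at percentile 97.52, just outside the middle 95% of random lists. Without ZMAT2 itself the shift was 0.23 at the 96.6th percentile, and with random lists matched on length too it stood at 97.47, just inside that range. SNRNP200, the helicase that unwinds U4 from U6, had a log2 ratio of 0.93 (0.90 to 0.96). U1 and U2 snRNP proteins had a shift of 0.09 with 1 of 30 higher, SF3A2 at 1.11 (1.01 to 1.21), which shares 12.7% of its exon bases. Sm and LSm proteins (-0.07) and later spliceosome proteins (0.06) had no called member among 17 and 35. SR proteins and their kinases (-0.09) had 2 lower of 26 and hnRNP proteins (-0.09) 1 lower of 32, PTBP3 at -1.24 (-1.36 to -1.13). All of these lists but that of the tri-snRNP and B complex lay within the middle 95% of random lists.

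**Figure D3:**
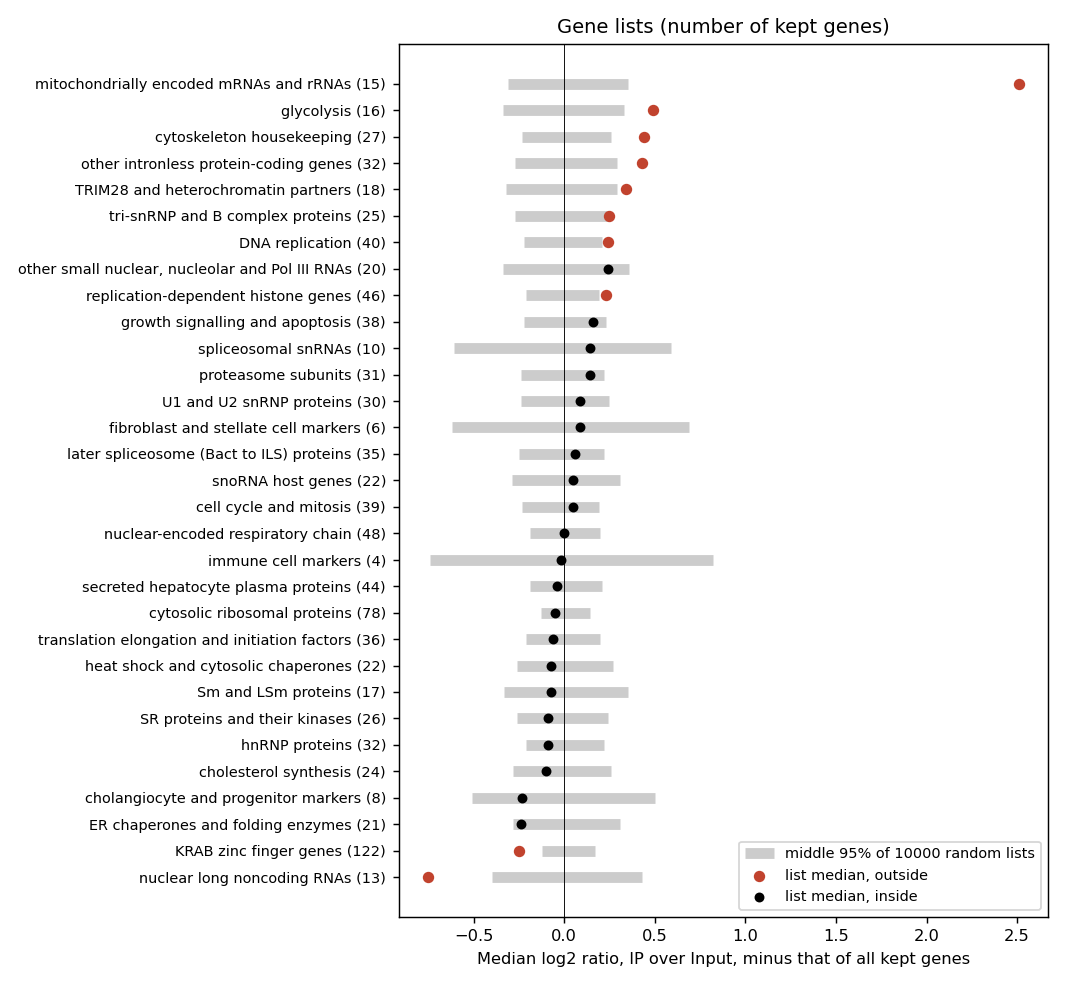
Each row is a gene list with its number of kept genes, its point the median log2 ratio of IP over Input minus that of all kept genes, and its grey bar the middle 95% of 10000 random lists matched on expression. Of 31 lists, 8 lay above the bar and 2 below it (red), and mitochondrial RNAs were farthest out at 2.51.

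Of the 31 lists with a shift, 8 lay above and 2 below the middle 95% of random lists. If list members were independent draws, 1.55 would lie outside by chance. Members of a list can share properties that were not matched, such as gene span, and some lists share members. The number 1.55 is therefore only a rough guide. TRIM28 and its heterochromatin partners had a shift of 0.34 at the 98.8th percentile, with TRIM28 the 1 called gene of 18. Of these, 10 lay above the median of all genes, the mean was 0.17, and the 95% interval of the shift, -0.37 to 0.75, included 0. CBX1 and CBX5, which encode forms of the heterochromatin protein HP1, had log2 ratios of -0.56 and -0.70. KRAB zinc finger genes, whose proteins recruit TRIM28, lay below all random lists with a shift of -0.25. Of the 122 kept, 31 were above the median of all genes, while 1 passed 2-fold in each direction. ZNF91 had a log2 ratio of -0.91 (-1.01 to -0.82).

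Glycolysis genes had a shift of 0.49 at the 99.7th percentile, and all 16 kept lay above the median of all genes, with 3 called higher. ENO1 had a log2 ratio of 0.49 (0.47 to 0.51), GAPDH, with 14.2% of exon bases shared, of 0.34 (0.32 to 0.36), and ENO2, with 54 and 6 reads, of 3.08 (1.97 to 4.69). DNA replication genes had a shift of 0.24 at the 98.7th percentile with 4 higher of 40, among them the polymerase delta subunit gene POLD1 (8.77% of exon bases shared) at 1.17 (1.02 to 1.32). The replicative helicase gene MCM7 (8.94% shared) was at 0.85 (0.81 to 0.89). Cytoskeleton housekeeping genes had a shift of 0.44 at the 99.9th percentile with 5 higher of 27, and MYH9 and KRT8, the latter at 0.74 (0.73 to 0.75) with 7.63% of exon bases shared, had the most reads. Histone genes, whose mRNAs have no introns, had a shift of 0.23 at the 98.9th percentile with 1 higher of 46. Matched on length too, the percentile was 94.4. Whether the mRNA kit kept histone mRNAs equally in both libraries was not tested. The list of other intronless protein-coding genes had a shift of 0.43 at the 99.8th percentile with 7 higher and 1 lower of 32. At a minimum of 1000 reads the percentile was 96.1. This list was not filtered on exon blocks, and some members have several, such as TOB2 with 2 and SOX9 with 3. Its shift is therefore not that of intronless genes alone. Farthest from the median of all genes was ZXDB, with 6 and 32 reads, at -2.31 (-3.95 to -1.12). JUNB, with 156 and 35 reads, had a log2 ratio of 2.15 (1.63 to 2.74) and shares 14.2% of its exon bases, chosen after its value was seen.

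Intron content was also compared over all nuclear protein-coding genes. The 314 genes with a single exon block had a median log2 ratio of 0.19 (0.08 to 0.26) and the 12624 with several a median of 0.01, a difference of 0.175, at the 99.96th percentile of expression-matched lists. These lists were not matched on exon length or gene span, so the difference cannot be assigned to introns alone. Of the single-exon genes, 30 were higher and 14 lower. The share of genes called higher was 9.55% with 1 exon block, 5.35% with 5 to 9 and 15.1% with 40 or more. The log2 ratio had a rank correlation of 0.03 with the number of exon blocks, -0.08 with exon length and -0.21 with gene span. With exon length and expression held fixed by partial rank correlation, it was 0.0998 with exon blocks and -0.202 with gene span, and with exon blocks and expression held fixed -0.113 with exon length. Without this, the correlation with exon blocks in 5 expression bins, from lowest to highest, was -0.0226, 0.00114, 0.0542, 0.0699 and 0.138.

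Other lists stayed within the range of random lists. Cytosolic ribosomal protein genes had a shift of -0.05 with 1 lower of 78, RPL22 at -1.06 (-1.08 to -1.03). The shift was -0.06 for translation factors, whose mean differed in sign at 0.06, 0.14 for proteasome subunits and -0.07 for heat shock proteins. Secreted hepatocyte plasma proteins had a shift of -0.04 with 1 lower of 44, and ALB and APOB stood at -0.53 (-0.54 to -0.52) and -0.69 (-0.71 to -0.68). ER chaperone genes had a shift of -0.24 at the 4.68th percentile, with none of 21 called. Cholesterol synthesis genes had a shift of -0.10 with 4 lower of 24, and the shift was 0.04 at a minimum of 1000 reads. Cell cycle genes had a shift of 0.05 with 1 higher of 39, TPX2, a spindle assembly factor, at 1.20 (1.17 to 1.23). Growth signalling and apoptosis genes had a shift of 0.16 at the 90.8th percentile, and of -0.03 at a minimum of 1000 reads. Markers of other cell types were mostly at few reads: 4 of 19 immune, 6 of 16 fibroblast and stellate and 2 of 13 endothelial markers were kept, with shifts of -0.02 and 0.09 for the first 2 lists and none given for the endothelial markers. At a minimum of 100 reads the fibroblast and stellate list moved to -0.27 and the immune list to -0.13. Cholangiocyte and progenitor markers had 8 of 11 kept and a shift of -0.23, which was -0.04 at a minimum of 100 reads and -0.28 at 1000.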

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

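Of the settings below, a minimum of 1000 reads, intervals on pairs of reads, genes with little shared exon sequence and the tri-snRNP list without ZMAT2 were chosen after seeing the data. Other scalings (library totals, totals without mitochondrial genes, DESeq2 size factors, upper quartile), prior count 5 and intervals on pairs of reads kept the numbers of higher and lower genes within 1.5 times 1328 and 1248. The number higher and lower was 2004 and 2014 with at least 1 read, 761 and 582 at a minimum of 100 reads, 329 and 191 at a minimum of 1000 reads, 467 and 397 with the interval wholly beyond 2-fold, 3196 and 2868 at 1.5-fold, 232 and 241 at 4-fold, and 852 and 649 for protein-coding genes only, as the smaller or larger sets of genes and sizes imply. Among genes sharing under 5% of their exon bases, 767 were lower, and the 914 higher ones stayed within 1.5 times. The correlation across genes was 0.9498 at a minimum of 100 reads and 0.9595 with log2 (CPM + 0.1). With library totals the log2 ratio was 2.72 for ZMAT2 and 1.02 for TRIM28, both still called higher. Of 541 recomputed values, 439 stayed within their error or 1.5 times, 102 moved and 0 reversed, where a gene counts as reversed if it was called and a list if it stood outside the range of random lists. Many of these values were ratios of named genes under other scalings. Those moved all ratios by nearly the same amount, at the most -0.106 for the median with library totals. A gene called at 2-fold could not reverse under them, so its not reversing says little. Inside that range, 6 shifts in 5 lists changed sign, all at other read minimums: spliceosomal snRNAs (-0.23 at 100 reads), other small RNAs (-0.20 at 100 and -0.17 at 1000), cholesterol synthesis (0.04 at 1000), growth signalling (-0.03 at 1000) and fibroblast markers (-0.27 at 100). Of 117 named genes, ZNF91 and RGS5 changed call, both to lower at -1.02 with library totals. In 152 recomputed list percentiles, 4 crossed the edge of the middle 95%, in 3 lists: tri-snRNP proteins (97.31 at a minimum of 100 reads, 97.47 matched on length), histone genes (94.37 matched on length) and other intronless genes (96.13 at a minimum of 1000 reads). The tri-snRNP list without ZMAT2, which is not among these 4, also fell inside that range, at 96.57. The matching and the partial correlations on GC content were not run, as no genome sequence was used here. No paired analysis was possible because each group holds 1 library. Depth limits the genes with few reads: 32.4% of those with 20 to 39 reads differed by 2-fold and were called, against 7.61% at 3000 or more.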

Other observations

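All gene families below were defined by name patterns among protein-coding genes, and the single genes named with them chosen, after the highest and lowest genes had been seen. The tests of mitochondrial DNA, of precursor RNA, of capture through proteins and of mates counted separately were also chosen only after the result was seen.

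Several families of actin-binding proteins stood high in the IP. All 5 spectrin genes kept were higher, with a shift of 2.45, as were all 6 filamin and alpha-actinin genes (2.19), 12 of 18 unconventional myosins (1.22), 4 of 9 myosin heavy chains (0.98, and 3.89 for the 4 with at least 1000 reads) and 3 of 4 tropomodulins and leiomodins (1.82). SPTBN1, which encodes a beta spectrin, had 297579 reads in the IP and 43267 in Input, a log2 ratio of 2.79 (2.78 to 2.81). Other genes with at least 1000 reads and high ratios were PLEC (2.94), UTRN (2.55), MPRIP (2.53), IQGAP1 (2.45) and DBN1 (2.44), whose proteins bind actin or link to it. AHNAK (2.51), NDEL1 (2.41), PTPN23 (2.39), NES (2.30) and IWS1 (2.29), which are not known chiefly as actin-binding, were also high. NDEL1 overlaps the span of MYH10 and shares 0.91% of its exon bases with another gene. Some of its reads may therefore be those of MYH10. No gene passed 2-fold among 6 myosin light chains (shift 0.16), 4 tropomyosins (-0.13), 9 members of the Arp2/3 complex (-0.08) and 7 keratins (0.45), and ACTB stood at 0.05. Tubulins (0.29), formins (0.38) and dyneins (-0.13) lay within the range of expression-matched random lists, as did kinesins (0.24), which lay at the 97.7th percentile when matched on length too. Each of these held called genes: 2 higher and 1 lower of 15 tubulins, 2 higher and 2 lower of 11 formins, among them DIAPH1 at 1.70 (1.67 to 1.73), 2 higher and 1 lower of 15 dyneins, among them DYNC1H1 at 1.09 (1.05 to 1.13), and 2 higher of 32 kinesins. Counted in pairs of reads, 1 higher call among the myosin heavy chains and 1 lower call among the formins were lost, and all other calls of the families named so far stayed. The first 5 families together had 30 higher and 0 lower of 42 genes and a shift of 1.49 (1.19 to 2.05), but they were joined because they stood high, so these values follow in part from that selection. With myosin light chains, tropomyosins, the Arp2/3 complex and formins added, 32 of 72 genes were higher and 2 lower, and the shift was 0.75 (0.39 to 1.22).

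Genes named as solute carriers stood lower in the IP. Of 269 kept, 46 were lower and 10 higher, with a shift of -0.21 (-0.30 to -0.06), below all random lists, also when matched on length, and of -0.28 for the 200 with under 5% of exon bases shared. Of 161 numbered TMEM genes, 20 were lower and 5 higher, with a shift of -0.17 at the 0.24th percentile, but its interval, -0.31 to 0.01, included 0. For the 43 with at least 1000 reads the shift was -0.56, and for the 80 solute carriers at that depth -0.26. In pairs of reads, 38 solute carriers stayed lower and 7 higher, and 20 and 3 TMEM genes. Matched on length too, the percentile of the TMEM genes was 0.15, and the 105 with little shared sequence had a shift of -0.19. Among protein-coding genes with at least 1000 reads, the lowest upper bounds belonged to SLC16A7, a monocarboxylate transporter gene, at -1.86 (-1.96 to -1.77), SELENOI, an ethanolamine phosphotransferase gene with 5.95% of exon bases shared, at -1.71 (-1.82 to -1.59), and SLCO4C1, an organic anion transporter gene, at -1.69 (-1.89 to -1.50).

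For the 5 actin families that stood high, the middle 95% of 10000 random lists matched on exon length and expression lay from -0.29 to 0.20. The matching used 5 bins each of length and expression, and the families' shift of 1.49 lay at the 100th percentile. The families were joined because they stood high, so this percentile follows in part from that selection. Over 12938 nuclear protein-coding genes, the rank correlation of the log2 ratio with exon length was -0.08. It was negative in each of 5 expression bins, at -0.01 in the highest. A general gain of longer transcripts would make it positive, so these values argue against length alone. The number of exon blocks was not matched. Reads shared with other genes are not enough to give the shift, as the 32 members with under 5% of exon bases shared kept a shift of 1.43. A candidate explanation is that mRNAs were captured through the proteins being made from them, by an antibody or beads that hold actin-bound proteins or, for ZMAT2's own mRNA, ZMAT2; myosin light chains, short members of the same machinery, had a shift of 0.16, but a preference of ZMAT2 for certain RNAs could also differ between long and short members, so the 2 cannot be told apart. The IgG control that would bear on binding to beads was not analysed here, and binding of these mRNAs by ZMAT2 itself stays open.

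For the mitochondrial RNAs, an even cover of mitochondrial DNA at the depth of the least covered gene would give 7.521% of the mitochondrial IP reads, and at that of the least covered mRNA gene 31.68%. Evenly covered DNA therefore does not account for most of these reads. The excess over Input is only a part of them, and what share of that excess DNA could give was not computed. Reads per base of tRNA genes relative to their neighbours were 20.7 times higher in the IP than in Input, with medians of 1.24 and 0.0597, and each of the 22 tRNA genes went this way. Reads longer than a tRNA gene inflate its reads per base, and whether they do so equally in both libraries was not tested, since fragment lengths are not given. Strand may not have been used in counting. Reads in tRNA genes of the minus strand, such as MT-TQ and MT-TA, may in that case come from RNA of the other strand. A larger share of uncut precursor RNA in the IP would raise this ratio. Evenly covered DNA would raise it too, since it adds equal reads per base to tRNA genes and their neighbours. A difference in which RNA pieces the library preparation kept could also give it. The ratio does not separate these readings, and the test was chosen with the ratios in view. A biological role of ZMAT2 in mitochondria was not tested.

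Ratios were widest among genes with few reads. Over genes with 20 to 39 reads the SD of the log2 ratio was 1.44, where counting of reads gives 0.55 and counting of pairs 0.85, so counting error alone is too small. There were 36 genes with 20 or more reads in one library and none in the other, where counting of pairs gives 0.903, so mates counted separately are not enough. Copies of few molecules made by amplification could give such counts in both libraries, which a table of summed reads cannot show, and no biological explanation was tested. At 3000 or more reads the SD was 0.75, against 0.04 from counting. A spread beyond counting error was thus not particular to genes with few reads.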
